A study of Ovis aries with 57 samples.

How the data were processed

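Conceptuses were flushed from the uterine horn, and pieces of the horn were frozen, sectioned and stained so that LE and GE could be told apart by eye and captured by laser. LE and GE RNA was amplified before library preparation, as was the RNA of day 12 conceptuses, while RNA of later conceptuses was not. The series text gives 4 samples per tissue without saying how animals were spread over the days, and each library was treated as a separate animal.

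Reads had been mapped by the authors to the sheep genome Oar v3.1, and the aligner, the counting rule and the annotation are not given in the sources used here. The RPKM values of LE and GE were made by the authors, per the file headers, from exon reads scaled to exon length and to mapped reads. For the conceptus the deposited gene read counts were used, which the authors had summed per gene before deposit. On day 12 these counts include reads outside exons, and on later days they are the reads that gave the RPKM, taken here as exon reads. The authors' own fold change between days, used as a score with a sign, and their FDR p-value came, per the file headers, from their EDGE test. The authors' tests served for a side by side count only. The tables hold 25197 features, and 23 of them had no identifier and were left out.

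Each RPKM value is a whole number of reads divided by exon length and depth. Depth per library and exon length for 18942 features were recovered from the values, and 100% of the low values tested came out whole within 0.1 read. The recovered depth shows that RPKM was scaled per library and not per tissue, so LE and GE were tested against each other. The plan foresaw counts for LE and GE, but their files hold RPKM, so limma was used for them.

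For LE and GE, limma with a mean-variance trend was run on log2(RPKM + 1), over genes at an RPKM of 1 or more in at least 4 samples, and a fold change is on that log2(RPKM + 1) scale. All days of a tissue entered 1 fit, and both tissues entered 1 fit for LE against GE and for the difference of changes. For the conceptus, edgeR's quasi-likelihood test with TMM scaling and its own filter was run on the gene reads of all days, a choice settled after several fits had been seen. Every adjusted p for a gene is Benjamini-Hochberg adjusted over all genes of the comparison by these tools, and genes with an adjusted p under 0.05 are said to rise or fall. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists and steps of the tissue. Lists with at least 5 measured genes were tested: 14 in LE, 16 in GE, 16 in the conceptus and 17 for LE against GE. Past the threshold were 17 of 56 tests in LE, 16 of 64 in GE, 8 of 48 in the conceptus and 34 of 85 for LE against GE. With the groups of the samples shuffled, a median of 8, 9, 9 and 11 tests passed it. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and Python 3.11.15.

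The groups, the comparisons, the tests, the lists, most of the other settings tried and the rule for naming genes were fixed before the data were examined. The rule allows, per comparison, the 6 largest rises and the 6 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 10 in the higher group and no overlap between the groups' libraries. It also allows up to 4 members with the smallest adjusted p per list past its test, and a fixed set of core genes. Between groups of 4 libraries each, chance alone leaves no overlap for 2.86% of genes. For LE against GE the largest differences were taken over genes called the same way at all 5 days. Among the genes so allowed, those in the text were picked after their values were seen. TOP2A, and GRP in LE on day 20, were chosen for that contrast after their values were seen.

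Neighbouring sample numbers of LE and GE could stand for the same animal, but the labels do not say so. Deviations from the group mean correlated between -0.065 and 0.194 for neighbouring numbers and between -0.184 and 0.12 for other samples of the day, and between -0.311 and 0.358 for conceptuses of the same number. The medians were 0.054 for neighbouring numbers and -0.012 for other LE and GE samples of the day, and 15 of 20 LE samples correlated best with the GE sample of the neighbouring number, where 5 would by chance. These values lean towards pairs. The tests stayed unpaired as planned, and the assumed pairs entered as a block among the other settings.

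In a test with 100 genes changed by a known fold in noise taken from these libraries, limma found 5% of 4-fold and 53% of 16-fold changes for LE from day 12 to 14, and 30 and 72% for GE. For the difference of changes it found 4 and 25%. For the conceptus edgeR found 79 and 84% from day 12 to 14, 88 and 98% from day 14 to 16, and 82 and 96% from day 16 to 20.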

Results

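RNA was sequenced from 3 tissues of pregnant sheep: the luminal epithelium (LE) that faces the uterine cavity, the glandular epithelium (GE), and the conceptus, the embryo with its membranes. LE and GE were cut out by laser from frozen uterine sections on days 10, 12, 14, 16 and 20 of pregnancy, with 4 libraries per tissue and day (20 of LE and 20 of GE). Conceptuses came from day 12 (n = 5) and days 14, 16 and 20 (n = 4 each), in all 17 libraries. Mapped reads ranged from 8.04 to 26.01 M per LE library, from 7.86 to 22.32 M in GE and from 14.62 to 27.38 M in the conceptus. Reads in exons ranged from 1.93 to 7.59 M in LE, from 1.76 to 6.37 M in GE and from 4.89 to 14.62 M in the conceptus. Mitochondrial genes held 10.02 to 35.48% of the exon reads in LE libraries and 0.40 to 17.41% in GE libraries. The LE libraries of day 14 listed 4528 to 5997 genes at an RPKM of 1 or more, against 6247 to 8741 in the other LE libraries, and the GE libraries of day 14 listed 6539 to 7916, against 7152 to 9161 in the other GE libraries. Values below are mean ± SD of 4 libraries (n = 5 on day 12 of the conceptus), in RPKM for LE and GE and in CPM (reads scaled to the TMM library size) for the conceptus. Gene symbols are those of the files.

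Between days 10 and 12 few genes were called in LE, though 829 of 9203 had an unadjusted p under 0.05 in limma. CST6, an inhibitor of cysteine proteases, rose from 13.0 ± 7.93 to 225 ± 161.8 RPKM (log2 change 3.73, adjusted p = 0.0051). LGALS15, a galectin released into the uterine lumen, rose from 196.1 ± 330.4 (688.3 in replicate 05) to 2270 ± 1399 RPKM (adjusted p = 0.00998). That value is uncertain because reads can be shared between near-identical galectin copies. RBP4, a retinol carrier, rose from 7.17 ± 5.91 to 321.4 ± 341.6 RPKM (adjusted p = 0.0218). HSD11B1, which regenerates cortisol, rose from 1.18 ± 2.26 to 89.06 ± 89.64 RPKM (adjusted p = 0.0138). CYBRD1, a ferric reductase, fell from 435.1 ± 126.5 to 31.4 ± 24.8 RPKM (log2 change -4.02, adjusted p = 0.00216). PSAT1, an enzyme of serine synthesis, fell from 65.09 ± 44.85 to 4.19 ± 4.95 RPKM (adjusted p = 0.0471).

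Of 22 measured genes known to answer to progesterone and interferon tau while the conceptus elongates, here called elongation genes, 8 rose, 11 when adjusted over the list alone (list adjusted p = 5.64e-10, and adjusted p = 0.147 with an estimated correlation). IGFBP1, a growth factor binding protein, rose from 11.11 ± 16.45 to 134.4 ± 64.43 RPKM (adjusted p = 0.0262). SLC5A1, a glucose carrier, rose from 0.45 ± 0.85 to 48.88 ± 50.08 RPKM (adjusted p = 0.0488). Of 24 genes of adhesion and matrix 1 rose, 6 when adjusted over the list alone (list adjusted p = 0.0296, and adjusted p = 0.464 with an estimated correlation). The integrin subunit ITGAV stood at 11.68 ± 5.62 and 41.39 ± 10.9 RPKM (adjusted p = 0.0798). The 39 interferon response genes had a median log2 change of 0.77 (list adjusted p = 0.00139, and adjusted p = 0.51 with an estimated correlation). Limma called 0 of them, with 7 at an unadjusted p under 0.05, and edgeR and DESeq2 on recovered reads called 0. The 17 genes of the unfolded protein response had a median of 1.07 (list adjusted p = 0.00204, and adjusted p = 0.327 with an estimated correlation). Limma, edgeR and DESeq2 called 0 of these 17, with 6 at an unadjusted p under 0.05 in limma.

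Limma called 29 genes higher and 23 lower among 9203 tested. Of the calls 55.8% were higher as deposited, and 27.6, 32.0 and 30.7% with RLE, upper quartile and TMM scaling. CST6 and CYBRD1 passed whichever of the 8 libraries was left out, and CYBRD1 was lost with edgeR on recovered reads. Each other gene said above to have changed was lost without day 10 replicate 01 or without 07, where the counts were 8 and 11; the count was 28 without 03, 15 without day 12 replicate 09, and 17 without 11 or 15.

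From day 12 to day 14 LE held more falls than rises as deposited, and more rises with upper quartile scaling. Cystatin C (listed as ENSOARG00000006202), a secreted protease inhibitor, rose from 264 ± 319.4 to 2213 ± 1050 RPKM (adjusted p = 0.00392), and CST6 rose to 1159 ± 179.4 RPKM (adjusted p = 0.00678). CCL2, a monocyte attractant, rose from 0.59 ± 0.67 to 54.47 ± 49.86 RPKM (adjusted p = 0.000703). TINAGL1, a matrix protein, rose from 2.27 ± 2.64 to 41.24 ± 21.06 RPKM (adjusted p = 0.000966). FST, an activin antagonist, rose from 17.96 ± 23.98 to 192 ± 126.1 RPKM (adjusted p = 0.0142). EFEMP1, a fibulin of the matrix, fell from 208.9 ± 108.8 to 14.3 ± 18.82 RPKM (adjusted p = 0.0124). CP, the copper carrier ceruloplasmin, fell from 225.4 ± 211.7 to 7.08 ± 7.05 RPKM (adjusted p = 0.00915). NUDT4, a phosphohydrolase, fell from 29.32 ± 2.94 to 0.38 ± 0.42 RPKM (log2 change -4.50, adjusted p = 7.15e-05).

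Among 22 elongation genes 4 rose and 1 fell, 7 and 2 when adjusted over the list alone (list adjusted p = 0.00963, and adjusted p = 0.51 with an estimated correlation). SLC2A1, a glucose carrier, rose from 65.54 ± 50.03 to 257.7 ± 78.42 RPKM (adjusted p = 0.0149). Of 39 interferon response genes 2 rose, 2 when adjusted over the list alone (median 0.22, list adjusted p = 0.0465, and adjusted p = 0.742 with an estimated correlation). RSAD2, an antiviral enzyme, rose from 3.17 ± 1.35 to 25.72 ± 17.59 RPKM (adjusted p = 0.0246) and CMPK2 from 3.29 ± 1.54 to 14.93 ± 10.93 RPKM (adjusted p = 0.0279). ISG17, the file's name for ISG15, stood at 14.2 ± 12.17 and 85.67 ± 57.7 RPKM (adjusted p = 0.0617). Of 14 antigen presentation genes 2 rose, 3 when adjusted over the list alone (list adjusted p = 0.00558, and adjusted p = 0.327 with an estimated correlation). PSMB9, a proteasome subunit, rose from 5.34 ± 2.43 to 79.71 ± 65.22 RPKM (adjusted p = 0.001). Of 11 steroid receptors and cofactors 3 fell, 4 when adjusted over the list alone (list adjusted p = 0.0465, and adjusted p = 0.359 with an estimated correlation). That list was lost with RLE (0.067) and TMM scaling (0.0552). PGRMC1, a progesterone receptor membrane component, fell from 9.86 ± 4.91 to 1.38 ± 2.36 RPKM (adjusted p = 0.00682). ESR2, an oestrogen receptor, fell from 4.46 ± 2.91 RPKM to a listing of 0 in all 4 libraries (adjusted p = 0.0136). Of 13 immediate early genes 1 fell, while 2 rose and 1 fell when adjusted over the list alone (median 0.96, list adjusted p = 0.0296, and adjusted p = 0.327 with an estimated correlation). The 17 unfolded protein response genes had a median of 0.56 (list adjusted p = 0.0491, and adjusted p = 0.551 with an estimated correlation). Limma called 0 of them, with 1 at an unadjusted p under 0.05, edgeR called 1 and DESeq2 2.

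In this step 312 genes rose and 898 fell, 25.8% higher as deposited, and 44.7, 70.1 and 39.4% with RLE, upper quartile and TMM scaling. The median log2 change of all tested genes was -0.341, and -0.137, 0.235 and -0.195 with those scalings. Without day 12 replicate 11 the count was 639 and SLC2A1, ESR2 and RSAD2 were lost, and without 13 it was 682 and FST and CMPK2 were lost. Day 14 replicates B02 and B04 also decided RSAD2, and day 12 replicates 09 and 15 and day 14 B08 decided CMPK2.

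From day 14 to day 16 LE held more rises than falls as deposited, and more falls with upper quartile scaling. ALDH1A1, which makes retinoic acid, rose from 24.83 ± 30.84 to 365.1 ± 72.92 RPKM (adjusted p = 0.00195). SLC36A2, an amino acid carrier, rose from 4.78 ± 3.72 to 100.6 ± 30.28 RPKM (adjusted p = 0.00756). LY6G6C, a membrane-anchored protein, rose from 0.050 ± 0.10 to 87.63 ± 74.3 RPKM (log2 change 5.99, adjusted p = 0.000588). POSTN, a matrix protein of stroma, fell from 109.1 ± 62.32 to 12.18 ± 6.47 RPKM (adjusted p = 0.015). NR4A1, an orphan nuclear receptor, fell from 11.46 ± 7.66 to 0.59 ± 0.59 RPKM (adjusted p = 0.0109). RPS26_2 fell from 252.9 ± 169.4 to 15.98 ± 10.43 RPKM (adjusted p = 0.00115), an uncertain value because this ribosomal gene has near-identical copies that can share reads.

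Of 13 stromal markers, written down to watch for other cells in the capture, 3 fell, 5 when adjusted over the list alone (median -1.64, list adjusted p = 4.1e-09, and adjusted p = 0.147 with an estimated correlation). COL3A1, a fibrillar collagen, fell from 11.26 ± 6.47 to 1.64 ± 1.09 RPKM (adjusted p = 0.0268), and VIM stood at 189.5 ± 206.8 and 21.9 ± 11.73 RPKM (adjusted p = 0.0725). Of 39 interferon response genes 3 rose and 1 fell, the same numbers when adjusted over the list alone, and the list moved down (median -0.12, list adjusted p = 0.0049, and adjusted p = 0.593 with an estimated correlation). IFI6 fell from 2539 ± 1205 to 541.5 ± 364.5 RPKM (adjusted p = 0.0327), while LGALS3BP rose from 1.44 ± 1.05 to 8.03 ± 2.73 RPKM (adjusted p = 0.0284). Of 14 antigen presentation genes 1 fell, 1 when adjusted over the list alone (list adjusted p = 0.00959, and adjusted p = 0.327 with an estimated correlation). It was PSMB9, at 13.36 ± 2.14 RPKM on day 16 (adjusted p = 0.0167). Of 17 unfolded protein response genes 1 fell, 0 when adjusted over the list alone (median -0.51, list adjusted p = 0.000729, and adjusted p = 0.327 with an estimated correlation). It was HERPUD1, which fell from 31.56 ± 12.83 to 7.76 ± 6.29 RPKM (adjusted p = 0.0456). Of 13 immediate early genes 1 rose and 2 fell, 1 and 3 when adjusted over the list alone. Their median of 0.02 lay above 0 while their mean of -0.27 and their test lay below it (list adjusted p = 0.0465, and adjusted p = 0.327 with an estimated correlation). That list was lost with RLE (0.101) and TMM scaling (0.0712).

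In all 1010 genes rose and 129 fell, 88.7% higher as deposited, and 62.5, 27.6 and 73.5% with RLE, upper quartile and TMM scaling. The median change of all tested genes was 0.492, and 0.142, -0.30 and 0.271 with those scalings. Without day 16 replicate 25 the count was 702 and POSTN and COL3A1 were lost, and without 31 it was 577 and LGALS3BP and HERPUD1 were lost. COL3A1, IFI6, LGALS3BP and HERPUD1 hung on 3, 4, 4 and 5 of the 8 libraries, while LY6G6C, SLC36A2, ALDH1A1, NR4A1, RPS26_2 and PSMB9 passed whichever was left out. Of these, SLC36A2 was lost with upper quartile scaling and with edgeR on recovered reads, and NR4A1 and PSMB9 in a fit of the samples of the 2 days alone.

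Few LE genes were called from day 16 to day 20, though 825 of 9203 had an unadjusted p under 0.05 in limma. CYP26A1, which breaks down retinoic acid, rose from 0.45 ± 0.55 to 45.89 ± 62.32 RPKM (adjusted p = 0.0143). SLC13A5, a citrate carrier, fell from 15.61 ± 8.59 to 0.56 ± 0.65 RPKM (log2 change -3.37, adjusted p = 0.00444). CD55, which restrains complement, fell from 94.2 ± 59.7 to 2.99 ± 5.57 RPKM (adjusted p = 0.0206). The 11 cell cycle genes had a median rise of 1.24 (list adjusted p = 1.57e-06, and adjusted p = 0.327 with an estimated correlation). Limma called 0 of them, 3 when adjusted over the list alone, with 5 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 2. TOP2A, of dividing cells, stood at 20.54 and 22.48 RPKM in replicates 21 and 23 of day 20 and at 0.010 and 0.67 in replicates 17 and 19. GRP, a gland product, stood in the same libraries at 224.5 and 719 against 2.89 and 0.63 RPKM. The 13 immediate early genes had a median of 0.66 (list adjusted p = 0.0262, and adjusted p = 0.327 with an estimated correlation). Limma called 0 of them, 1 when adjusted over the list alone, with 1 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. With replicates 21 and 23 left out the lists had adjusted p = 0.179 and 0.29 in limma's camera. In all 10 genes rose and 14 fell, 41.7% higher as deposited and 20.0% with upper quartile scaling. The count was 123 without day 20 replicate 19, 9 without 21, and 10, 13 and 14 without day 16 replicates 25, 29 and 27. CYP26A1 was lost in 3 and CD55 in 5 of the 8 fits with 1 library left out, and SLC13A5 in 0, and all 3 were lost with edgeR on recovered reads. Of 35 splits of the 8 samples into other groups, the real one included, 2 gave as many calls.

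In GE few genes were called from day 10 to day 12, though 830 of 10049 had an unadjusted p under 0.05 in limma. S100G, a calcium-binding protein, fell from 7248 ± 2741 to 754.6 ± 309 RPKM (log2 change -3.31, adjusted p = 0.00567). SERPINA1, a protease inhibitor, fell from 22.32 ± 10.69 to 2.82 ± 2.14 RPKM (adjusted p = 0.00343). MEP1B, a metalloprotease, rose from 12.84 ± 10.55 to 99.65 ± 57.72 RPKM (adjusted p = 0.000883). IFI6, an interferon-induced gene, rose from 29.84 ± 39.09 (88.22 in replicate 04) to 440.5 ± 293.7 RPKM (adjusted p = 0.00159). It was the 1 of 40 interferon response genes that rose, 1 when adjusted over the list alone (median 0.39, list adjusted p = 9.75e-06, and adjusted p = 0.643 with an estimated correlation). The 14 markers of ciliated cells, which occur in uterine glands, had a median rise of 1.36 (list adjusted p = 4.07e-09, and adjusted p = 0.19 with an estimated correlation). Limma called 0 of them, 2 when adjusted over the list alone, with 10 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 5. The 20 elongation genes had a median of 0.64 (list adjusted p = 0.0173, and adjusted p = 0.234 with an estimated correlation). Limma called 0 of them, with 4 higher and 1 lower at an unadjusted p under 0.05, edgeR called 0 and DESeq2 3. The 17 unfolded protein response genes had a median of -0.59 (list adjusted p = 0.00319, and adjusted p = 0.242 with an estimated correlation). Of these limma called 0, 1 when adjusted over the list alone, with 4 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0. Limma called 18 genes higher and 35 lower among 10049 tested. The count was 29 and 30 without day 10 replicates 02 and 08, and 32, 32 and 33 without day 12 replicates 10, 12 and 16, while the genes named here passed in every such fit. SERPINA1 was lost with a pseudocount of 0.1 and with DESeq2 and edgeR on recovered reads.

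Between days 12 and 14, 34 of 40 interferon response genes rose in GE. RSAD2 rose from 1.55 ± 0.77 to 132.1 ± 56.06 RPKM (log2 change 5.64, adjusted p = 1.6e-05). IFIT3, which binds viral RNA complexes, rose from 3.26 ± 2.89 to 117.2 ± 98.63 RPKM (adjusted p = 1.7e-05). ISG17, which tags proteins, rose from 1.75 ± 1.14 to 179.7 ± 222.6 RPKM (adjusted p = 0.000198) and MX1 from 10.48 ± 7.16 to 176.1 ± 127 RPKM (adjusted p = 0.000452). NAA38, of an acetyltransferase complex, fell from 29.11 ± 7.96 to 1.42 ± 1.18 RPKM (adjusted p = 1.6e-05). OST, the file's name for osteopontin, fell from 8.66 ± 5.2 to 0.47 ± 0.55 RPKM (adjusted p = 0.00714).

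Of 40 measured interferon response genes 34 rose, and when adjusted over the list alone 39 rose and 1 fell (median 2.34, list adjusted p = 1.62e-31, and adjusted p = 0.0765 with an estimated correlation). Of 16 antigen presentation genes 9 rose, 10 when adjusted over the list alone (median 1.31, list adjusted p = 2.46e-06, and adjusted p = 0.0729 with an estimated correlation). PSMB9 rose from 4.53 ± 0.84 to 83.17 ± 63.58 RPKM (adjusted p = 1.32e-05) and the peptide transporter TAP1 from 2.53 ± 0.62 to 11.9 ± 6.51 RPKM (adjusted p = 0.00373). Of 5 endothelial markers 1 rose, 1 when adjusted over the list alone (list adjusted p = 0.0397, and adjusted p = 0.279 with an estimated correlation). It was VWF, which rose from 6.54 ± 2.53 to 52.95 ± 24.18 RPKM (adjusted p = 0.000152). In total 632 genes rose and 973 fell. The count was 975 without day 12 replicate 12 and 951 without 16, while the genes named here passed whichever library was left out.

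**Figure D1:**
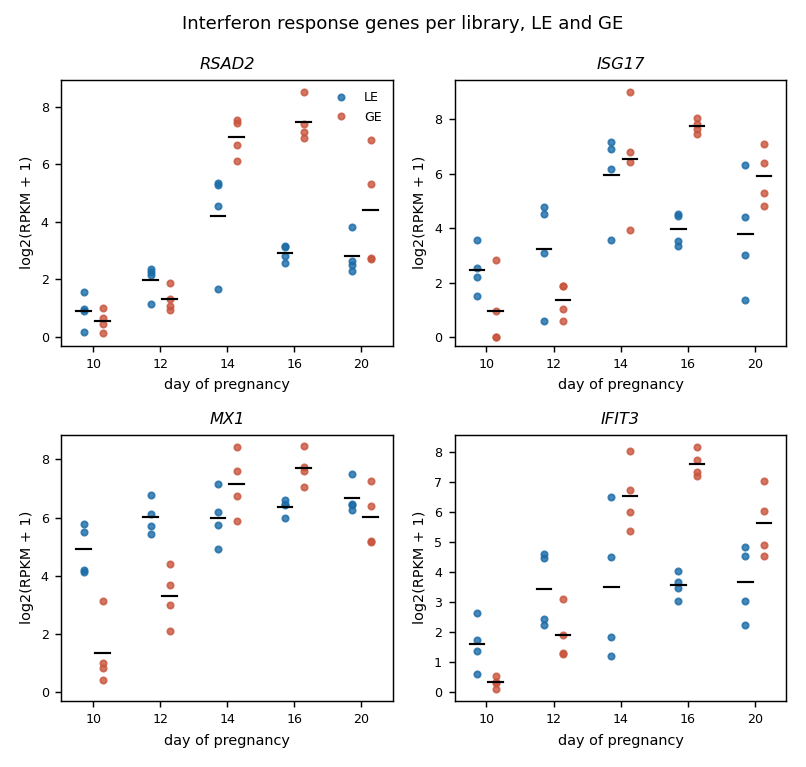
Log2(RPKM + 1) of RSAD2, ISG17, MX1 and IFIT3 against the day of pregnancy, with 1 dot per library (LE blue, GE red, 4 per tissue and day) and a black bar at the mean of the log2 values. RSAD2 lies between 0.93 and 2.66 RPKM in the GE libraries of day 12 and between 69.23 and 186.2 RPKM in those of day 14. In the LE libraries of day 16 it lies between 4.89 and 8.03 RPKM.

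From day 14 to day 16, 9 of 40 interferon response genes rose and 5 of 11 stromal markers fell in GE, and both lists were lost with an estimated correlation. IP-10, a chemokine that attracts T cells, rose from 6.20 ± 7.54 to 51.5 ± 11.25 RPKM (adjusted p = 0.000898). IFI44 rose from 11.82 ± 4.56 to 33.91 ± 5.11 RPKM (adjusted p = 0.00881). PLA1A, a phospholipase, rose from 5.10 ± 5.37 to 52.23 ± 25.92 RPKM (adjusted p = 0.000492). PLTP, a phospholipid carrier, fell from 17.25 ± 5.72 to 0.91 ± 0.47 RPKM (adjusted p = 2.39e-05). PGR, the progesterone receptor, rose from 4.72 ± 4.23 to 22.21 ± 19.63 RPKM (adjusted p = 0.0127), and ESR1, an oestrogen receptor, fell from 117.3 ± 76.41 to 35.08 ± 12.07 RPKM (adjusted p = 0.0352). Of 40 interferon response genes 9 rose, 11 when adjusted over the list alone (median 1.00, list adjusted p = 0.0085, and adjusted p = 0.851 with an estimated correlation). Of 11 stromal markers 5 fell, 5 when adjusted over the list alone (median -1.05, list adjusted p = 0.000382, and adjusted p = 0.203 with an estimated correlation). COL1A1, a fibrillar collagen, fell from 38.86 ± 30.09 to 2.05 ± 1.07 RPKM (adjusted p = 0.0051). PDGFRB, a growth factor receptor, fell from 3.35 ± 1.14 to 0.68 ± 0.22 RPKM (adjusted p = 0.0134). Of 5 endothelial markers 1 fell, 1 when adjusted over the list alone (list adjusted p = 0.0208, and adjusted p = 0.241 with an estimated correlation). It was again VWF, at 13.18 ± 5.53 RPKM on day 16 (adjusted p = 0.00327). In all 1268 genes rose and 491 fell, 72.1% higher as deposited, and 54.3, 57.1 and 57.7% with RLE, upper quartile and TMM scaling. The median change of all tested genes was 0.254, and 0.082, 0.109 and 0.112 with those scalings. The count was 1168 without day 16 replicate 28 and 1110 without 30. PGR was lost without day 16 replicate 26, and ESR1 without day 14 B03 or B05 or day 16 replicates 28, 30 or 32.

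From day 16 to day 20, 4 of 12 gland secretion genes rose in GE. GRP, a gastrin-releasing peptide, rose from 74.63 ± 75.82 to 4989 ± 2497 RPKM (log2 change 7.40, adjusted p = 0.00581). OST rose from 5.72 ± 4.79 to 412.9 ± 200.6 RPKM (log2 change 6.10, adjusted p = 1.55e-05). SERPINA14, the uterine serpin, rose from 40.96 ± 12.06 to 2326 ± 1781 RPKM (adjusted p = 0.00926). STC1, a calcium-regulating hormone, rose from 1.12 ± 1.02 to 60.3 ± 60.08 RPKM (adjusted p = 0.00133). INHBA, an activin subunit, rose from 4.31 ± 5.43 to 61.17 ± 18.96 RPKM (adjusted p = 0.0016). SEC11C, of the signal peptidase, rose from 5.41 ± 3.13 to 190.1 ± 75.58 RPKM (adjusted p = 0.000974). Of 12 gland secretion genes 4 rose, 4 when adjusted over the list alone (median 0.96, list adjusted p = 1.11e-10, and adjusted p = 0.00241 with an estimated correlation). Of 20 elongation genes 4 rose, while 7 rose and 1 fell when adjusted over the list alone (median 0.38, list adjusted p = 1.2e-10, and adjusted p = 0.00241 with an estimated correlation). The 4 of both lists are GRP, OST, SERPINA14 and STC1. Of all list calls in this text, these 2 are the ones that held with an estimated correlation.

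In the same step 2 of 40 interferon response genes fell, 21 when adjusted over the list alone (median -1.25, list adjusted p = 3.35e-23, and adjusted p = 0.134 with an estimated correlation). RSAD2 fell from 198.3 ± 113.9 to 40.94 ± 50.96 RPKM (adjusted p = 0.0412). IFIT2 fell from 125.3 ± 39.31 to 24.26 ± 22.42 RPKM (adjusted p = 0.0251). The 16 antigen presentation genes had a median of -0.72 (list adjusted p = 0.000314, and adjusted p = 0.134 with an estimated correlation). For these limma, edgeR and DESeq2 made 0 calls, with 4 at an unadjusted p under 0.05 in limma. The 12 steroid receptors and cofactors had a median of -0.69 (list adjusted p = 0.00319, and adjusted p = 0.241 with an estimated correlation). Here limma made 0 calls, 1 when adjusted over the list alone, with 5 at an unadjusted p under 0.05, edgeR made 0 and DESeq2 1. The 10 prostaglandin genes had a median of 0.23 (list adjusted p = 0.00221, and adjusted p = 0.108 with an estimated correlation). Among them limma, edgeR and DESeq2 made 0 calls, with 2 at an unadjusted p under 0.05 in limma. In all 12 genes rose and 19 fell, 38.7% higher as deposited, 68.4% with RLE or upper quartile scaling and 66.7% with TMM. The count was 12, 15 and 12 without day 16 replicates 26, 28 and 30, and 20, 11 and 11 without day 20 replicates 018, 020 and 022. GRP, OST, STC1, INHBA and SEC11C passed in all 8 fits. Of these, GRP and INHBA were lost with a pseudocount of 0.1 and with edgeR on recovered reads, and INHBA with DESeq2 too. SERPINA14 was lost without day 20 replicate 022, RSAD2 in 7 fits and IFIT2 in 6, and RSAD2 and IFIT2 also with each of the 3 scalings.

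**Figure D2:**
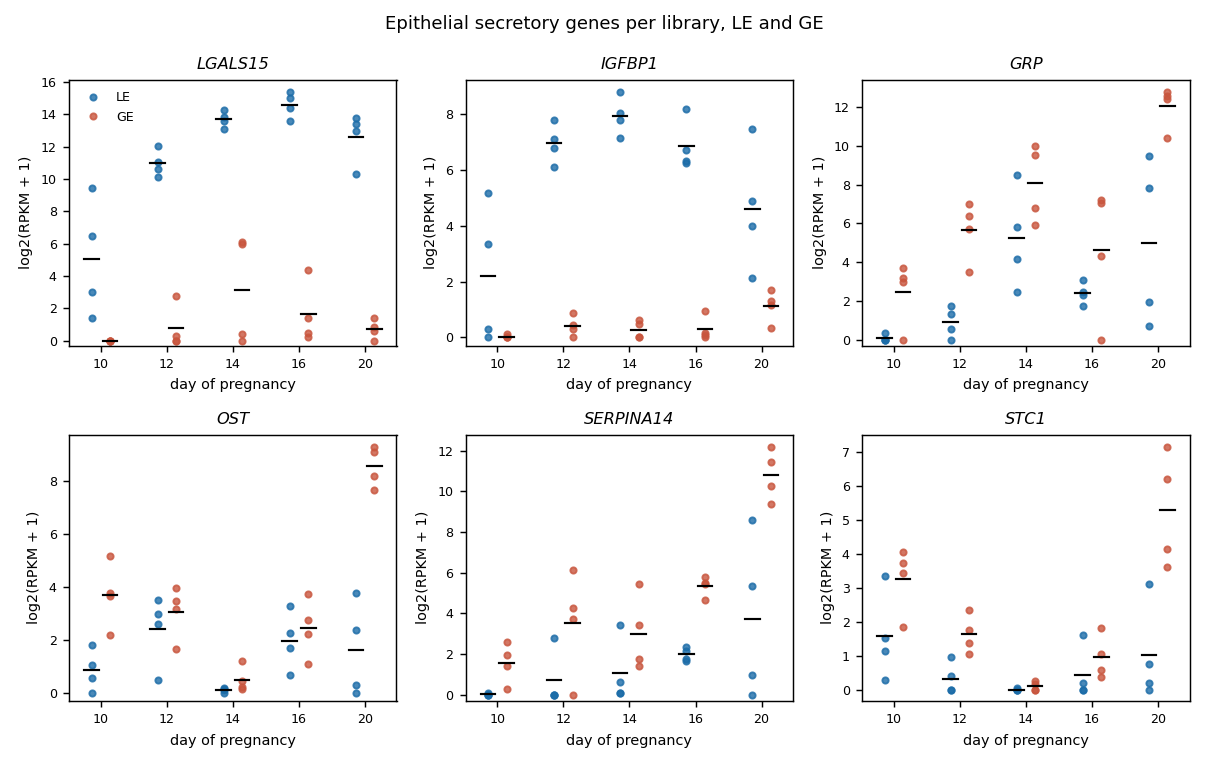
Log2(RPKM + 1) of LGALS15, IGFBP1, GRP, OST, SERPINA14 and STC1 against the day of pregnancy, with 1 dot per library (LE blue, GE red, 4 per tissue and day) and a black bar at the mean of the log2 values. LGALS15 lies between 12270 and 42110 RPKM in the LE libraries of day 16 and between 0.19 and 19.75 RPKM in those of GE. OST in GE moves from between 1.13 and 12.32 RPKM on day 16 to between 197.7 and 617.3 RPKM on day 20.

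LE and GE of the same day were compared to ask how the surface epithelium differs from that of the glands. At all 5 days 51 genes were higher in LE and 192 higher in GE. These counts rest on the RPKM as deposited and were not repeated with other scalings. On the single days, given below, scaling moved the balance towards LE. ANXA1, a phospholipid-binding annexin, stood on day 10 at 437.6 ± 127.4 RPKM in LE against 5.91 ± 2.06 in GE (adjusted p = 8.05e-11). PEPT1, a peptide carrier, stood on day 16 at 249.4 ± 69.26 against 0.85 ± 0.37 RPKM (adjusted p = 1.44e-10). GE carried more PRLR, the prolactin receptor, with 111.1 ± 28.78 RPKM on day 20 against 0.87 ± 1.15 in LE (adjusted p = 1.36e-11). IL6ST, a receptor subunit of the interleukin 6 family, stood on day 10 at 581.8 ± 93.74 RPKM in GE against 13.93 ± 7.77 in LE (adjusted p = 2.62e-11). LGALS15 stood on days 12, 14, 16 and 20 at 2270, 13850, 27070 and 8507 RPKM in LE against 1.51, 32.91, 5.51 and 0.74 in GE. These tests are unpaired.

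On day 10, 5 of 40 interferon response genes were higher in LE, 5 when adjusted over the list alone (list adjusted p = 1.68e-07, and adjusted p = 0.283 with an estimated correlation). MX1 stood at 33.06 ± 18.87 RPKM in LE against 2.43 ± 3.49 in GE (adjusted p = 1.92e-05). Of 17 unfolded protein response genes 6 were lower in LE, 6 when adjusted over the list alone (list adjusted p = 0.0124, and adjusted p = 0.328 with an estimated correlation). The chaperone HSPA5 stood at 17.12 ± 9.44 in LE against 73.62 ± 24.51 RPKM in GE (adjusted p = 0.00126). Of 15 prostaglandin genes 3 were higher and 1 lower, 3 and 1 when adjusted over the list alone (list adjusted p = 0.00653, and adjusted p = 0.159 with an estimated correlation). HPGD, which inactivates prostaglandins, stood at 1.92 ± 1.65 against 41.06 ± 4.84 RPKM (adjusted p = 4.21e-06). Of 24 elongation genes 3 were higher and 2 lower, 7 and 3 when adjusted over the list alone (list adjusted p = 0.00332, and adjusted p = 0.284 with an estimated correlation). Of 18 glucose and amino acid carriers 2 were higher and 3 lower, 4 and 3 when adjusted over the list alone (list adjusted p = 0.0395, and adjusted p = 0.285 with an estimated correlation). The last 2 lists were lost with RLE (0.0624 and 0.162) and TMM scaling (0.0637 and 0.135). Among 11131 tested genes 295 were higher in LE and 1295 in GE, 18.6% higher in LE as deposited, and 50.2 and 50.4% with RLE and TMM scaling. The median log2 difference of all genes was -0.454, and -0.035 and -0.032 with those scalings.

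On day 12, 8 of 24 elongation genes were higher and 7 of 15 ciliated cell markers lower in LE, and both lists were lost with an estimated correlation. IGFBP1 stood at 134.4 ± 64.43 RPKM in LE against 0.36 ± 0.36 in GE (adjusted p = 1.92e-07). PTGS2, the inducible prostaglandin synthase, stood at 247.7 ± 81.99 against 1.48 ± 1.26 RPKM (adjusted p = 5.83e-08). Of 24 elongation genes 8 were higher and 1 lower in LE, 9 and 2 when adjusted over the list alone (list adjusted p = 7.34e-09, and adjusted p = 0.0539 with an estimated correlation). Of 15 ciliated cell markers 7 were lower in LE, 8 when adjusted over the list alone (list adjusted p = 0.000592, and adjusted p = 0.358 with an estimated correlation). DNAH5, a motor of cilia, stood at 1.65 ± 1.00 against 20.87 ± 6.78 RPKM (adjusted p = 4.82e-07). Of 12 steroid receptors and cofactors 5 were lower in LE, 5 when adjusted over the list alone (list adjusted p = 0.0321, and adjusted p = 0.277 with an estimated correlation). That call was lost with RLE (0.0634) and TMM scaling (0.0733). Of 40 interferon response genes 3 were higher, 3 when adjusted over the list alone (list adjusted p = 4.69e-07, and adjusted p = 0.284 with an estimated correlation). Of 14 stromal markers 2 were higher, 2 when adjusted over the list alone (list adjusted p = 0.0109, and adjusted p = 0.367 with an estimated correlation). Of 15 prostaglandin genes 3 were higher and 1 lower, 3 and 1 when adjusted over the list alone. Their median of -0.16 lay below 0, and their mean of 0.64 and their test above it (list adjusted p = 0.0132, 0.0508 with TMM scaling, and adjusted p = 0.201 with an estimated correlation). Of 27 adhesion genes 5 were higher, while 5 were higher and 1 lower when adjusted over the list alone. Here too the median of -0.02 lay below 0, and the mean of 0.54 and the test above it (list adjusted p = 0.00565, and adjusted p = 0.276 with an estimated correlation). In all 337 genes were higher in LE and 1021 in GE, 24.8% higher in LE as deposited, and 48.0 and 52.6% with RLE and TMM scaling.

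On day 14, 22 of 40 interferon response genes were lower in LE, 23 when adjusted over the list alone (median -1.39, list adjusted p = 0.00127, and adjusted p = 0.465 with an estimated correlation). RSAD2 stood at 25.72 ± 17.59 RPKM in LE against 132.1 ± 56.06 in GE (adjusted p = 0.00129). Of 12 steroid receptors and cofactors 9 were lower in LE, 9 when adjusted over the list alone (median -2.44, list adjusted p = 0.000559, and adjusted p = 0.103 with an estimated correlation). ESR1 stood at 24.91 ± 31.44 (71.77 in replicate B04) against 117.3 ± 76.41 RPKM (adjusted p = 0.000561). Of 24 elongation genes 10 were higher and 1 lower, 10 and 1 when adjusted over the list alone (list adjusted p = 1.26e-06, and adjusted p = 0.103 with an estimated correlation). CST6 stood at 1159 ± 179.4 against 19.18 ± 26.91 RPKM (adjusted p = 5.95e-09). Of 15 ciliated cell markers 10 were lower, 12 when adjusted over the list alone (list adjusted p = 0.0135, and adjusted p = 0.5 with an estimated correlation). Of 15 prostaglandin genes 3 were higher and 1 lower, 3 and 1 when adjusted over the list alone (list adjusted p = 0.00834, and adjusted p = 0.16 with an estimated correlation). Of 17 unfolded protein response genes 4 were higher and 1 lower, 4 and 1 when adjusted over the list alone (list adjusted p = 0.00549, and adjusted p = 0.284 with an estimated correlation). Of 20 immune cell markers 7 were lower and 1 higher, a list not past its test (list adjusted p = 0.295, and 0.000754 with limma's fry test). Of 8 endothelial markers 3 were lower and 1 higher (0.874, and 0.0461 with fry). Fry asks whether a list changed at all, and camera whether it changed more than the other genes. On this day all tested genes had a median log2 difference of -0.464. In all 974 genes were higher in LE and 3011 in GE, 24.4% higher in LE as deposited, and 41.4 and 40.6% with RLE and TMM scaling.

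On day 16, 34 of 40 interferon response genes were lower in LE, 37 when adjusted over the list alone (median -2.57, list adjusted p = 2.22e-16, and adjusted p = 0.103 with an estimated correlation). ISG17 stood at 15.73 ± 6.77 RPKM in LE against 215.6 ± 39.85 in GE (adjusted p = 0.00214). Of 16 antigen presentation genes 8 were lower, while 9 were lower and 1 higher when adjusted over the list alone (list adjusted p = 0.00834, and adjusted p = 0.268 with an estimated correlation). Of 20 immune cell markers 9 were lower and 1 higher, 9 and 1 when adjusted over the list alone (list adjusted p = 0.0458, and adjusted p = 0.4 with an estimated correlation). The granule protease GZMA stood at 9.70 ± 6.75 against 75.85 ± 17.02 RPKM (adjusted p = 5.35e-05). Of 12 steroid receptors and cofactors 7 were lower, while 9 were lower and 1 higher when adjusted over the list alone (list adjusted p = 0.00132, and adjusted p = 0.106 with an estimated correlation). PGR stood at 0.68 ± 0.51 against 22.21 ± 19.63 RPKM (adjusted p = 7.59e-06). Of 24 elongation genes 11 were higher and 1 lower, 13 and 1 when adjusted over the list alone (list adjusted p = 7.34e-09, and adjusted p = 0.0539 with an estimated correlation). Of 15 prostaglandin genes 5 were higher, 6 when adjusted over the list alone (list adjusted p = 0.000117, and adjusted p = 0.0539 with an estimated correlation). Of 27 adhesion genes 6 were higher, 6 when adjusted over the list alone (list adjusted p = 0.000251, and adjusted p = 0.137 with an estimated correlation). The integrin subunit ITGB6 stood at 11.8 ± 3.82 against 0.44 ± 0.45 RPKM (adjusted p = 1.29e-06). Of 15 ciliated cell markers 5 were lower, 7 when adjusted over the list alone (list adjusted p = 0.0229, and adjusted p = 0.524 with an estimated correlation). In all 753 genes were higher in LE and 1750 in GE, 30.1% higher in LE as deposited, and 47.9 and 50.5% with RLE and TMM scaling.

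On day 20 the gland products GRP and OST were higher in GE. GRP stood at 236.7 ± 338.2 RPKM in LE against 4989 ± 2497 in GE (adjusted p = 0.00052) and OST at 4.22 ± 5.85 against 412.9 ± 200.6 (adjusted p = 5.49e-09). Of 14 gland secretion genes 5 were lower in LE and 0 higher, 5 and 3 when adjusted over the list alone, and the list was not past its test (list adjusted p = 0.289). Of 24 elongation genes 11 were higher and 7 lower in LE, 12 and 7 when adjusted over the list alone (list adjusted p = 0.00118, and adjusted p = 0.275 with an estimated correlation). Of 27 adhesion genes 5 were higher and 1 lower, 11 and 1 when adjusted over the list alone (list adjusted p = 0.000117, and adjusted p = 0.115 with an estimated correlation). The surface mucin MUC16 stood at 22.28 ± 13.44 against 0.11 ± 0.13 RPKM (adjusted p = 7.25e-05). Of 14 immediate early genes 5 were higher, 6 when adjusted over the list alone (list adjusted p = 0.00427, and adjusted p = 0.159 with an estimated correlation). Of 17 cell cycle genes 4 were higher, 6 when adjusted over the list alone (list adjusted p = 8.2e-05, and adjusted p = 0.277 with an estimated correlation). Replicates 21 and 23 carried the cell cycle list in LE: without them it had an adjusted p of 0.993 and went the other way, and the immediate early list had 0.0594. Of 15 prostaglandin genes 3 were higher and 1 lower, 4 and 1 when adjusted over the list alone (list adjusted p = 0.00844, and adjusted p = 0.16 with an estimated correlation). Interferon response genes were lower in LE for 9 of 40, 24 when adjusted over the list alone (list adjusted p = 1.96e-06, and adjusted p = 0.321 with an estimated correlation). Ciliated cell markers were lower for 3 of 15, 9 when adjusted over the list alone (list adjusted p = 0.00118, and adjusted p = 0.367 with an estimated correlation). Immune cell markers were lower for 2 of 20, 2 when adjusted over the list alone (list adjusted p = 0.0435, and adjusted p = 0.4 with an estimated correlation). In all 477 genes were higher in LE and 717 in GE, 39.9% higher in LE as deposited, and 52.6 and 55.6% with RLE and TMM scaling. The count was 744 without LE day 20 replicate 21 and 456 without replicates 21 and 23 together.

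Whether the epithelia changed differently was tested as the change in LE minus the change in GE. From day 12 to day 14 the change in LE was called lower for 14 of 40 interferon response genes. The difference of log2 changes was -3.90 for MX1 (adjusted p = 0.00623), -4.58 for IFIT3 (adjusted p = 0.0153) and -3.41 for RSAD2 (adjusted p = 0.038). It was 4.61 for FST (adjusted p = 0.0357) and -4.80 for CP (adjusted p = 0.0266). From day 10 to day 12 it was -6.13 for CYBRD1 (adjusted p = 0.000587) and 4.79 for HSD11B1 (adjusted p = 0.0249). From day 14 to day 16 it was 5.61 for LY6G6C (adjusted p = 0.000882) and 3.74 for ALDH1A1 (adjusted p = 0.0491). From day 16 to day 20 it was -6.46 for OST (adjusted p = 0.000395) and 3.84 for CYP26A1 (adjusted p = 0.00975). Of 100 splits of the samples into other groups, the real one included, 6 gave as many calls in the step from day 12 to 14. The change was called higher and lower in LE for 22 and 17 genes in the first step, 86 and 205 in the second, 351 and 112 in the third, and 26 and 26 in the fourth. Of these 56.4, 29.6, 75.8 and 50.0% were higher as deposited, and 41.5, 40.5, 64.7 and 35% with RLE scaling. The first count was 25 without LE day 12 replicate 09, 22 and 23 without GE day 10 replicates 02 and 08, and 25 and 24 without GE day 12 replicates 12 and 16. The second was 174 and 532 without LE day 12 replicate 11 and day 14 B02, 179, 184 and 144 without GE day 12 replicates 12, 14 and 16, and 458 without GE day 14 B07. The third was 732 without LE day 14 B04, 290 and 247 without LE day 16 replicates 25 and 31, and 278, 239 and 271 without GE day 16 replicates 26, 28 and 30. The fourth was 34 without LE day 16 replicate 29 or 31 or GE day 16 replicate 30, 89 and 18 without LE day 20 replicates 19 and 21, and 22 and 24 without GE day 20 replicates 020 and 022.

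In the conceptus, days 12 to 14 cover the time of elongation. TP-1, the file's name for a gene of interferon tau, the pregnancy signal of ruminants, rose from 194.4 ± 135.1 to 14110 ± 1651 CPM (log2 change 6.18, adjusted p = 1.97e-06). Its level is uncertain because near-identical interferon tau copies can share reads. PTGS2 rose from 515.9 ± 210.2 to 11120 ± 7596 CPM (adjusted p = 7.27e-07). PPARG2, the file's name for the lipid-sensing receptor PPARG, rose from 0.64 ± 0.32 to 65.32 ± 4.56 CPM (adjusted p = 2.39e-10). IL17F, an interleukin 17, had no read on day 12 and stood at 341.6 ± 258.3 CPM on day 14, at least 8240-fold higher against a floor of 3 reads over the group (adjusted p = 1.07e-05). NANOG, a pluripotency factor, fell from 6.26 ± 2.28 to 0.53 ± 0.14 CPM (adjusted p = 2.53e-06). NRCAM, a neuronal adhesion gene, fell from 338.2 ± 179.8 to 0.18 ± 0.10 CPM (adjusted p = 3.2e-09). CDX2, a trophectoderm factor, rose from 7.07 ± 1.67 to 23.73 ± 3.57 CPM (adjusted p = 7.66e-06). Of 33 cell cycle genes 20 rose and 5 fell, 20 and 5 when adjusted over the list alone (median 0.84, list adjusted p = 0.0191, and adjusted p = 0.888 with an estimated correlation). MCM3, which unwinds DNA for replication, rose from 24.84 ± 5.45 to 238.3 ± 32.48 CPM (adjusted p = 1.21e-11) and PCNA from 47.77 ± 11.36 to 278.6 ± 41.27 CPM (adjusted p = 4.59e-10).

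In total 5300 genes rose and 5286 fell among 13918 tested in edgeR. Day 12 RNA was amplified before sequencing and that of later days was not, so day and amplification cannot be told apart in this step. Of the gene reads of day 12 libraries 53.5 to 61.6% lay outside the recovered exon reads, against 0.3 to 0.6% later. On later days 100% of the RPKM values gave the deposited reads, so where an exon length was recovered those are exon reads. This step thus sets reads counted over whole genes on day 12 against reads taken as exon reads on day 14. The median log2 change ran from 0.60 among genes with up to 20% of their day 12 reads outside exons to -1.39 among those with 95% or more. With exon reads in place of gene reads on day 12, 10059 genes were called, of which 7552 held their direction and 807 turned it. Log2 changes on exon and gene reads were -9.92 and -10.8 for NRCAM, 3.23 and 4.43 for PTGS2, and 1.51 and 2.54 for PCNA. They were 3.19 and 1.75 for CDX2 and 7.74 and 6.64 for PPARG2. GATA6, a factor of primitive endoderm, fell from 37.24 ± 10.2 to 9.54 ± 2.66 CPM on gene reads (log2 change -1.97, adjusted p = 4.93e-06) and had a log2 change of 1.09 on exon reads.

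From day 14 to day 16, 19 of 30 yolk sac genes, 8 of 11 endothelial and 6 of 10 immune cell markers rose in the conceptus, and the 3 lists were lost with an estimated correlation. AFP, alpha-fetoprotein, rose from 24.99 ± 12.94 to 1039 ± 984.1 CPM (log2 change 5.38, adjusted p = 0.000452). FOXI1, a forkhead factor, rose from 0.16 ± 0.035 to 16.8 ± 6.5 CPM (adjusted p = 1.93e-06). SLC27A6, a fatty acid carrier, fell from 2200 ± 286 to 33.13 ± 20.12 CPM (log2 change -6.05, adjusted p = 0.000156). PTGES, a prostaglandin E synthase, fell from 65.93 ± 24.99 to 2.20 ± 0.82 CPM (adjusted p = 1.31e-05), and PTGS2 fell to 1485 ± 815.4 CPM (adjusted p = 0.000385). Of 30 genes of extraembryonic endoderm and yolk sac 19 rose and 2 fell, 20 and 3 when adjusted over the list alone (median 2.48, list adjusted p = 0.00837, and adjusted p = 0.805 with an estimated correlation). ALB, albumin, rose from 0.53 ± 0.56 to 14.08 ± 8.46 CPM (adjusted p = 5.19e-05), while LRP2, of receptor-mediated uptake, fell from 4959 ± 905.7 to 1267 ± 328.5 CPM (adjusted p = 4.72e-05). Of 11 endothelial markers 8 rose, 8 when adjusted over the list alone (median 2.75, list adjusted p = 0.0187, and adjusted p = 0.805 with an estimated correlation). TIE1, a vascular receptor, rose from 0.86 ± 0.25 to 6.76 ± 3.38 CPM (adjusted p = 6.92e-05). Of 10 immune cell markers 6 rose, 6 when adjusted over the list alone (median 1.90, list adjusted p = 0.0191, and adjusted p = 0.522 with an estimated correlation). AIF1, a macrophage gene, rose from 6.57 ± 3.13 to 33.74 ± 6.46 CPM (adjusted p = 3.59e-05). In all 3562 genes rose and 3384 fell, 51.3% higher as fitted and 64.8% with upper quartile scaling, which moved the median change of all genes from 0.058 to 0.235.

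From day 16 to day 20, 4 of 5 secreted products of the trophoblast rose, a list that was lost with an estimated correlation. TP-1 fell from 4819 ± 2036 to 301.9 ± 284.8 CPM (adjusted p = 0.00122) and PTGS2 to 173.8 ± 23.58 CPM (adjusted p = 0.000489). ESM1, a product of vessel cells, had no read on day 16 and stood at 97.71 ± 72.65 CPM on day 20, at least 1930-fold higher (adjusted p = 1.18e-05). DKK4, a Wnt antagonist, rose from 0.071 ± 0.10 to 75.06 ± 37.8 CPM (adjusted p = 1.49e-06). SLC34A2, a phosphate carrier, fell from 272 ± 116.2 to 2.49 ± 1.33 CPM (log2 change -6.77, adjusted p = 2.51e-07). Of 5 secreted products of the trophoblast 4 rose and 1 fell, 4 and 1 when adjusted over the list alone (median 6.60, also with PAG6 at its bound, list adjusted p = 0.00837, and adjusted p = 0.522 with an estimated correlation). The pregnancy-associated glycoprotein PAG11 rose from 0.42 ± 0.48 to 75.34 ± 50.88 CPM (adjusted p = 3.21e-05) and PAG4 from 50.62 ± 25.5 to 349.1 ± 165.9 CPM (adjusted p = 0.00548). PAG6 had no read on day 16 and stood at 7.28 ± 4.78 CPM on day 20, at least 144-fold higher (adjusted p = 0.00146). PRP2, related to prolactin, rose from 0.018 ± 0.036 to 2.51 ± 0.85 CPM (adjusted p = 8.66e-05). These 4 genes belong to families whose near-identical copies can share reads, so their separate values are uncertain. Of 16 immediate early genes 9 rose, 9 when adjusted over the list alone (median 0.99, list adjusted p = 0.00837, and adjusted p = 0.524 with an estimated correlation). NR4A2, an orphan receptor, rose from 1.51 ± 0.79 to 14.15 ± 6.78 CPM (adjusted p = 0.000245). Of 33 cell cycle genes 18 fell, 19 when adjusted over the list alone (median -0.54, list adjusted p = 5.4e-05, and adjusted p = 0.805 with an estimated correlation). CDC6, which licenses replication origins, fell from 80.11 ± 13.4 to 26.95 ± 2.84 CPM (adjusted p = 0.00013). Of 11 epiblast and pluripotency genes 6 fell, 6 when adjusted over the list alone (median -0.98, list adjusted p = 0.0187, and adjusted p = 0.731 with an estimated correlation). SALL4 fell from 21.95 ± 3.42 to 6.80 ± 2.26 CPM (adjusted p = 6.63e-05). In all 2516 genes rose and 2624 fell, and the genes named for the conceptus passed whichever library was left out.

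**Figure D3:**
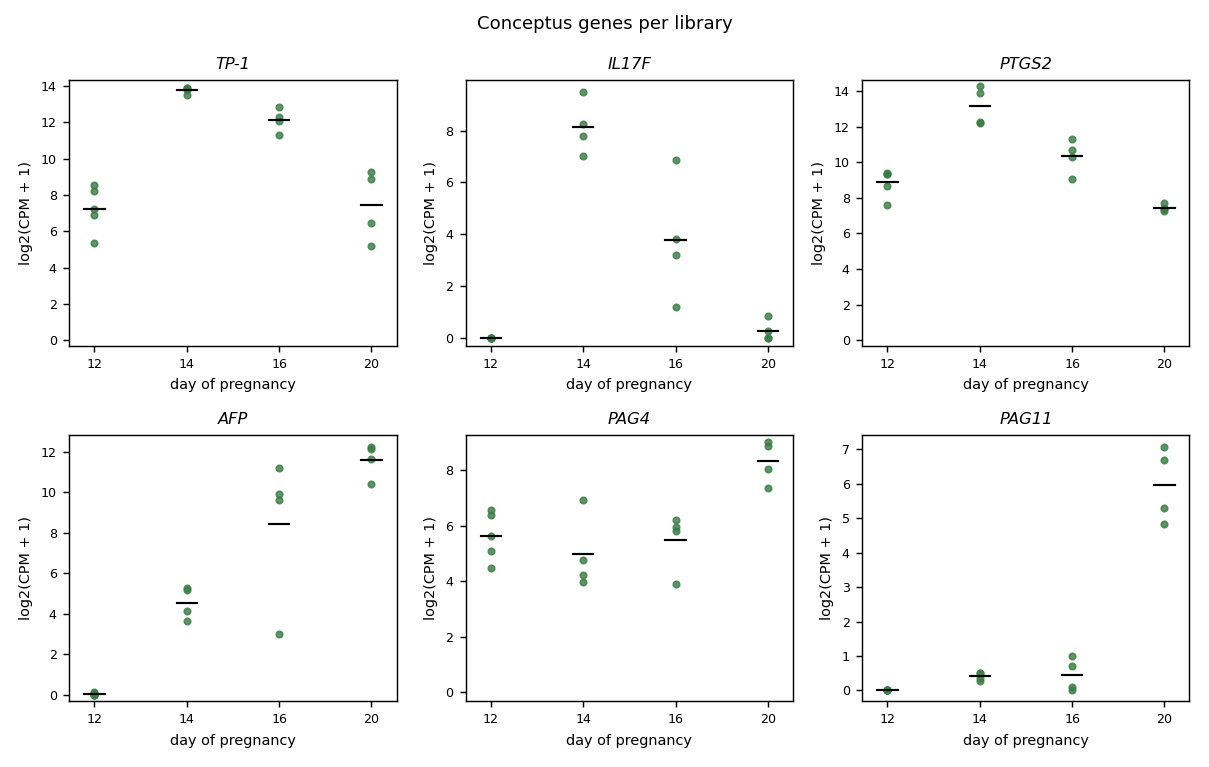
Log2(CPM + 1) of TP-1, IL17F, PTGS2, AFP, PAG4 and PAG11 in the conceptus against the day of pregnancy, with 1 green dot per library (n = 5 on day 12, n = 4 on days 14, 16 and 20) and a black bar at the mean of the log2 values. TP-1 lies between 40.15 and 367.6 CPM on day 12, between 11850 and 15420 CPM on day 14 and between 36.02 and 618.9 CPM on day 20. PAG11 lies between 0 and 1.00 CPM on day 16 and between 27.41 and 133.6 CPM on day 20.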

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

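The tests of batch, scaling, gene length and divided libraries at day 14, of conceptus tissue and of cell cycle genes in LE day 20, of uterine RNA in the day 12 conceptuses, and the splits of the gene lists and of LE and GE, except those of days 12 to 16, were chosen after the result was seen, and the way gland cells were judged was made stricter after it.

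Some libraries stood far from the other 3 (or 4) of their group. Over 570 gene and group values 61 did so (10.7%), where chance gives about 1 in 20 for normally spread values. The rule was applied to RPKM and CPM without logarithm, for genes picked after their values were seen. The 1 in 20 is thus no fair reference. In 10 of the 61 all other libraries of the group held the same value, mostly 0, which fixes the outcome of the rule, and without these it was 51 of 560 (9.1%). In LE day 10 replicate 05 LGALS15 stood at 688.3, PTGS2 at 152.2, HSD11B1 at 4.57 and SLC5A1 at 1.72 RPKM, and in replicate 03 KIAA1324 at 0.48. In LE day 12 replicate 09 cystatin C stood at 743.1 and SLC2A1 at 140.4. In LE day 14 B06 these were GRP 358.6, COL15A1 86.29, CA1 42.81, PRLR 0.65, LY6G6C 0.20 and PRSS16 0.10, and in B04 DDA1 343.3, ESR1 71.77, TRIM21 8.14, PGRMC1 4.91 and NQO1 0.48. B08 held GATM at 6.35 and FKBP5 at 18.24, and B02 held KIAA1324 at 0.01. LE day 16 replicate 27 held IL6R at 1.67. In LE day 20 replicate 23 CD55 stood at 11.34 and SERPINA14 at 379.4, and in 19 ANXA1 at 610.1 and PRSS16 at 0.05.

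In GE day 10 replicate 04 IFI6 stood at 88.22 and MX1 at 7.65, and in 08 PRSS16 at 276 and PDIA6 at 88.18. On day 12, replicate 12 held BCAT1 at 159 and PEPT1 at 1.38, 10 held IFIT2 at 3.95 and CST6 at 4.53, 16 held LGALS15 at 5.79 and 14 held PRSS16 at 107.2. On day 14, B07 held PSMB9 at 177.7. B01 held DRAP1 at 96.52, PEPT1 at 6.04 and YPEL5 at 4.35. B03 held PRLR at 197.9 and CDC42SE2 at 0.29, and B05 held ARL6IP5 at 10.52, MITD1 at 4.65 and CMC4 at 4.09. On day 16, replicate 28 held PRSS16 at 6.16 and PTGS2 at 1.97, 30 held LGALS15 at 19.75 and 32 held PDGFRB at 1.01. On day 20 replicate 018 held BACE2 at 9.17. In the conceptus, day 12 replicate 3 held CBLN4 at 80.64 CPM, day 14 replicate 1 MT-CO2 at 4147, replicate 2 SH2D4B at 30.82 and replicate 4 ARHGDIB at 13.12 and BBOX1 at 0.8301. On day 16 replicate 4 held BBOX1 at 132.4, CYR61 at 5.573 and METTL7B at 0.0724, replicate 5 NPPC_2 and PRP2 at 0.0715 each, and replicate 1 IL17F at 113.9.

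A test of the difference between the changes in LE and GE called 39 genes from day 10 to 12, 291 from day 12 to 14, 463 from day 14 to 16 and 52 from day 16 to 20. For the 291, and so for the genes of the second step below, chance stays open. Of 100 splits of the samples, the real one included, 6 gave as many, but the splits cannot decide this. They moved samples between days within each tissue, and some reversed the days of GE, so changes between days enter their counts. These splits, and those of LE against GE below, took no account of possible pairs of LE and GE samples. The log2 change in LE minus that in GE was -6.13 for CYBRD1, 4.79 for HSD11B1, 3.81 for C8orf4, 2.72 for SERPINA1 and 2.39 for PDIA6 in the first step. In the second it was 4.61 for FST, 3.54 for TINAGL1, -4.80 for CP, -4.65 for CA1, -4.58 for IFIT3, -3.90 for MX1, -3.86 for QPCT, -3.78 for NUDT4, -3.42 for IFIT2, -3.41 for RSAD2, -3.02 for ESR2 and -2.95 for CMPK2. In the third it was 5.61 for LY6G6C, 5.58 for R3HDM4, 4.87 for SLC36A2, 4.70 for CRIP2, 4.23 for AP2S1, 4.15 for CRYGS, 3.74 for ALDH1A1, 2.82 for LGALS3BP and 2.63 for PLTP. It was -3.45 for TMEM100, -3.16 for MITD1, -3.0 for IFI44L, -2.53 for NR4A1 and -2.21 for FOSL1. In the fourth it was 3.84 for CYP26A1, 3.5 for PFKFB3, 2.81 for ME2, -6.46 for OST, -5.44 for CRYGS, -5.27 for SEC11C, -5.14 for CD55, -3.74 for STC1, -3.62 for INHBA, -3.23 for SLC13A5 and -2.11 for KIAA1551.

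Of the genes called at day 14, 506 in LE (41.8%) and 994 in GE (61.9%) were called the other way by day 16. Both steps share the day 14 libraries, which by itself favours such a return. With these libraries divided so that the steps shared none, 123 to 185 genes in LE and 405 to 448 in GE did so over 6 divisions, against 48.2 to 93.2 and 145.1 to 187.1 for independent lists. In GE at least 67% of these genes were still called both ways under each of 4 other scalings, which argues against scaling as the whole cause there, while in LE it was 30.4% at the lowest, so scaling stays open. After a correction for gene length 91.3 and 84.5% were still called both ways, but the correction moved genes by a median of 0.037 and 0.034 only, which leaves gene length open (a first correction, which also removed library medians and was replaced after its result was seen, left 36.2 and 73.3%). Day 14 samples bear B numbers that 0 samples of another day bear, so a batch and the day cannot be told apart. These libraries lay apart from all others on the first principal component, at -45.7 to -115.6 in LE and -47.3 to -122.2 in GE, against -2.8 to 41 and -1.9 to 36.3. They also listed fewer genes, with a mean of 5326 in LE and 7256 in GE, against 7054 and 8517 on day 12 and 7458 and 8488 on day 16. In GE 0 of the 34 interferon response genes that rose fell back by limma, and the stage of pregnancy stays open as an untested biological explanation.

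LE day 20 replicates 21 and 23 stood apart from 17 and 19. For 11 cell cycle genes the excess over 17 and 19 would need a median of 576 and 410% of the GE level, or 30.2 and 21.8% of the conceptus level. This argues against gland cells and against conceptus tissue as a whole as the source of these transcripts in both libraries, since panels of other genes of those sources stood far lower. LE RNA was amplified and that of day 20 conceptuses was not, so each conceptus share also carries any effect of amplification on its gene. A panel of 12 gland genes had a median of 2.15 and 4.49% of its GE level and an upper quartile of 5.55 and 13.6%, and GRP stood at 4.5 and 14.4%. In replicate 21 OST stood at 0.23 RPKM, STC1 at 0.17, INHBA at 0.03 and PRLR at 0, against 412.9, 60.3, 61.17 and 111.1 in GE, which goes against gland cells, while the panel's upper quartile lay near the GRP share, so for the gland products they stay open. A panel of 100 conceptus genes had a median of 0.0177 and 0.187% of its conceptus level. Its upper quartile was 0.199% in replicate 21, which argues against conceptus tissue as a whole there, and 1.22% in 23, where a small share stays open. In replicate 21, however, PAG4 stood at 4.89 RPKM (12.3% of its conceptus level), PRP2 at 6.78 (against 1.985 in the conceptus) and TP-1 at 2.09 (against 432.8), so trophoblast cells of 1 kind, which were not tested, stay open there, for its cell cycle transcripts as well. In replicate 23 PAG4 stood at 2.85%, PRP2 at 0 and TP-1 at 7.15 RPKM, and in 17 and 19 TP-1 stood at 0. A difference between animals was not tested.

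The day 12 conceptuses held 6 transcripts of uterine epithelium that later conceptuses held below an RPKM of 1. They stood at a median of 29.2% of the LE level, from 17.6 to 45.6% by library, and 83.3% of them lay within 5-fold of the median share, so uterine cells or RNA carried along may be the source. CP stood at 65.85, PTPN22 at 74.19, CFTR at 19.03 and ACMSD at 16.56 RPKM, 29.1 to 33.8% of their LE level. ENSOARG00000002875 stood at 7.139 RPKM (8.59%) and APOD at 1.812 RPKM (2.33%), and the low share of APOD goes against 1 common share for all. Of genes higher in LE 91.7% were seen (11 of 12), and of genes higher in GE 26.5% (13 of 49, Fisher exact p = 5.46e-05), a ratio of 3.46 that argues against amplification as the whole cause. Expression by the conceptus itself was not tested.

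The same samples were split into other groups, and the calls of each split were counted. No share below 1 of 35 is possible with 35 splits, and many such tests were made. A count that the real split alone reached therefore makes chance less likely but does not exclude it. For LE from day 10 to 12, 1 of 35 splits was as large, the real one (52 calls, highest other 2). The same held from day 12 to 14 (1210, 130) and 14 to 16 (1139, 126). For LE from day 16 to 20, 2 of 35 splits were as large (24, 44), so chance could account for that count. For GE 1 of 35 was as large in each step, the real one (53 and 1, 1605 and 58, 1759 and 107, 31 and 2). The same held for LE against GE on the 5 days, with 1 of 35 (1590 and 108, 1358 and 3, 3985 and 1758, 2503 and 6, 1194 and 179), and for the step from day 12 to 16 in LE (117 and 1) and GE (204 and 0). On day 14 the other splits of LE against GE had a median of 607 calls, against 0 on the other days. For the differences of changes 1, 6, 3 and 1 of 100 splits were as large (39 and 28, 291 and 732, 463 and 677, 52 and 22). From day 12 to 14 chance thus stays open, and these splits cannot decide it. From day 14 to 16 another split also gave more calls than the real one. Splits that keep most samples of 1 tissue at their day, or that reverse the days of GE, carry changes between days. The counts of 732 and 677 may come from such splits, which was not tested. In the conceptus 1 of 100, 1 of 35 and 1 of 35 splits were as large, in each step the real one (10586 and 7894, 6946 and 459, 5140 and 14). For list calls 6, 10, 63 and 1 of 100 splits were as large in LE, GE, the conceptus and LE against GE (17 and 24, 16 and 23, 8 and 26, 34 and 23). For the last alone no other split reached the count.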

How the results depend on the processing

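Tests with TMM scaling of the RPKM, edgeR on recovered reads, exon reads on day 12, limma on conceptus RPKM, the step from day 12 to 16 and the fits without LE day 20 replicates 21 and 23 were chosen after seeing the data. Of the values of named genes and lists under the alternatives, 4542 held their direction and their side of the threshold, 595 lost a call, 19 gained one and 3 reversed. Of the 3, 2 are GATA6 in the conceptus from day 12 to 14, with log2 changes of 1.09 on exon reads and 1.34 in limma on RPKM against -1.97. The other is the cell cycle list of LE against GE on day 20, with an adjusted p of 0.993 in the other direction without LE replicates 21 and 23. Causes not given below were not tested.

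With upper quartile scaling LE calls were 25 from day 10 to 12 and 5 from day 16 to 20, and GE calls from day 16 to 20 were 19, as with RLE scaling (19), and 18 with TMM scaling. A pseudocount of 0.1 gave 31, 1826, 1730 and 5 calls in the 4 LE steps, and 29 and 16 in the first and last GE steps. Without the filter on low values the first difference of changes had 61 calls.

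DESeq2 on recovered reads gave 134, 2703, 2262 and 146 calls in LE, 182, 3009, 2884 and 54 in GE, and 69, 1739, 1905 and 108 for the differences of changes. For LE in the test with known changes, 37 of 126 DESeq2 calls were false. edgeR on recovered reads gave 4 and 1 calls in the first and last LE steps, 6 in the last GE step, 805 and 779 for LE against GE on days 10 and 12, and 2, 878, 1080 and 4 for the differences of changes.

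A fit of the samples of the 2 days alone gave 234, 418, 456 and 13 calls in LE and 104, 468, 291 and 65 in GE. A fit of that day's samples alone gave 2659, 2921 and 785 calls for LE against GE on days 10, 12 and 14. Without LE day 20 replicates 21 and 23, calls were 8 for LE from day 16 to 20, 456 for LE against GE on day 20 and 32 for the last difference of changes.

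The step from day 12 to 16 had 117 calls in LE and 204 in GE, 6 in LE with edgeR on recovered reads, and 499 and 461 with the day 14 samples left out of the fit.

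With 1 library left out, LE calls ranged from 8 to 67, 639 to 1571, 577 to 1614 and 9 to 123 in the 4 steps. GE calls ranged from 29 to 64, 951 to 2098, 1110 to 2302 and 11 to 44. LE against GE ranged from 1100 to 1529, 933 to 1099, 3696 to 4103, 1951 to 2072 and 744 to 1327 over the 5 days. The differences of changes ranged from 22 to 52, 144 to 532, 239 to 732 and 18 to 89, and the step from day 12 to 16 from 19 to 100 in LE and 136 to 172 in GE. Conceptus calls ranged from 10250 to 10447, 5855 to 6863 and 4139 to 5278. List calls ranged from 10 to 19 in LE, 14 to 19 in GE and 7 to 13 in the conceptus.

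The conceptus number as a replicate block gave 10413, 5925 and 4594 calls. An assumed animal as a replicate block gave 1555, 1395, 4040, 2503 and 1194 calls for LE against GE, and 26, 270, 423 and 47 for the differences of changes. On days 16 and 20 the totals equal those without the block, and 2307 and 1075 calls were shared.

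With an estimated correlation list calls were 0 in LE (17 with the preset one and 2 with fry), 2 in GE (16 and 11 with fry), 0 in the conceptus (8 and 28 with fry) and 0 for LE against GE (34 and 32 with fry).

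Depth was similar in both epithelia, and the LE libraries of day 14 listed the fewest genes.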

Other observations

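LE and GE shared more calls than independent lists would in the 2 steps that use the day 14 libraries. Batch and day cannot be told apart there, so a shift of batch or scaling shared by both tissues could give the same overlap. Among 8529 genes tested in both, 87 rose and 170 fell in LE and GE from day 12 to 14, against 17.9 and 88.9 for independent lists, and 11 went opposite ways. From day 14 to 16, 178 rose and 31 fell in both, against 128.5 and 5.3, and 26 went opposite ways. Correlations of the changes across genes, which are not independent replicates, were 0.166, 0.379, 0.261 and 0.034 over the 4 steps.

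A step that skips day 14 was added after seeing the data. From day 12 to day 16, 87 genes rose and 30 fell in LE, and 186 rose and 18 fell in GE. The LE count of 117 fell to 19, 42 and 45 without day 12 replicates 11, 13 and 15, and to 57, 67, 36 and 26 without day 16 replicates 25, 27, 29 and 31. The interferon response genes of GE that rose from day 12 to 14 had a median log2 change of 3.32 from day 12 to 16, and 0 of the 34 fell back by limma.

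The authors' own tests, counted towards the later day, gave 487 genes higher and 152 lower in LE from day 12 to 14 and 133 and 185 from day 14 to 16, against 312 and 898, and 1010 and 129 here. For GE they gave 801 and 222, then 236 and 604, against 632 and 973, then 1268 and 491 here. Of the calls made in both, 423, 229, 741 and 617 in these 4 steps, each went the same way. In the conceptus 4487 genes were called in both from day 12 to 14, of which 218 went opposite ways. How the authors' tests scaled the values is not given in the sources used here, and scaling moved the balance of higher and lower calls here as well.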
